A study of Mus musculus with 18 samples.

How the data were processed

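RNA of 18 samples of mouse cells was labelled in 1 colour and hybridised to Agilent whole-genome arrays, 2 samples in each of 9 groups, per the labels. Spot signals were extracted by the submitters with Agilent Feature Extraction 9.1.3.1, per the file headers, under 2 extraction protocols, and the background-subtracted, detrended signals are in the unit intensity, not scaled between arrays, per the file headers. The authors also deposited a table of means and standard errors per group, intensity normalized to the array median by the authors, which was used only as an alternative. Its values matched the means of the array signals over the array median. All comparisons start from the array signals, which were put on the log2 scale here, since the deposited intensity is linear.

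Each of the 43379 spots that are not controls was read, spots of the same probe were averaged, and 137 probes with outlier flags were left out. The log2 signal minus the log2 of the array's 75th percentile was the level of a probe. Of 41174 probes, 22951 were named through the reference table of accessions, 9755 through their symbol, and 8468 kept the name in the files; 8913 genes had several probes. Probes had to be well above background, by the extraction's own flag, on both arrays of at least 1 group, which 28114 probes were. The probe with the highest mean level then stood for its gene, which gave 18876 genes, 14891 of them with a gene name. No spot was saturated. The arrays give no counts, so their signal over background sets what can be measured.

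The 9 groups were fitted together with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with 9 residual degrees of freedom, a prior of 2.39 degrees of freedom and a prior SD of 0.289. The 9 comparisons named in the results were drawn from this fit by moderated two-sided tests, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each comparison. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Where a called gene was not well above background on any array of its lower group, its fold change is a lower bound, written as at least N-fold: the higher group's mean level against the mean, over the arrays of the lower group, of the gene's level or, if that is higher, of the lowest level at which a probe on the array was well above background. Where both groups were dim, no fold is given.

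The choice of comparisons, lists, tests, alternatives and the rule for named genes was made before the data were examined. In each comparison the text may name a panel (Dppa3, Dazl, Pou5f1, Nanog, Ddx4 and Kit), the 6 named genes called with the largest rise and the 6 with the largest fall that separated the groups and were well above background on both arrays of the higher group, and up to 4 called members per direction of each list, those with the smallest p. A feature outside this rule is said to be so where it is named.

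There were 28 gene lists, written from textbook knowledge: naive, general and primed pluripotency, 2-cell-like state, early PGC, gonadal germ cell, piRNA pathway, meiosis, spermatogonia, spermatid, germline RNA binding, DNA methylation, imprinted, mesoderm, endoderm, neural ectoderm, trophoblast, Hox, fibroblast, Sertoli, Leydig, erythroid, macrophage, endothelial, cell cycle, apoptosis, stress and immediate-early, and glycolysis genes. They were tested with camera at its preset correlation of 0.01, with camera's estimated correlation and fry beside it, and the p-values were adjusted over the 252 tests of 28 lists in 9 comparisons. A further 7 lists, chosen after the data were seen, served the closing tests and were adjusted over their own 56 tests. Agreements between comparisons are correlations across genes.

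The arrays lay on 6 slides, scanned on 4 days. Slides that held both groups of a comparison gave within-slide values and a fit with slide as a block. Day 7 filled slides of its own, and the E13.5 and juvenile groups shared a slide without cultured cells, so comparisons of either with other cells in culture have no such value. Replicate numbers served as a block only in an alternative. Self-tests on data simulated for the Dazl sort recovered 22 and 66 of 100 genes shifted by a log2 of 1 and 2. They called 1 of 18656 genes left alone and, without any true change, 1 of 18876 for Stella day 7. These rates need not hold where slides or spreads differ.

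The alternatives were quantile normalization, normexp background correction with an offset of 50, low signals floored, no filter on dim probes or a stricter filter, the mean over a gene's probes, an intensity trend in the prior, slide or replicate number as a block, a fit of only the arrays compared, a log2 fold change of at least 1, leaving out each library, and the authors' group means, floored at 0.1, for 13533 genes. Leaving out the library labelled E13.5 replicate 1 everywhere, and agreements without shared slides, were added after the data were seen. A count stayed the same when within 1.5 times.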

Results

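RNA from 18 samples was measured on one-colour Agilent mouse arrays, 2 arrays in each of 9 groups, to follow gene expression from embryonic stem (ES) cells to germ cells derived from them in culture and to germ cells taken from the animal. There were 4 groups of ES cells, sorted into cells positive and negative for green fluorescent protein (GFP), from a line that carries a reporter for Stella, the protein encoded by Dppa3, and from a line that carries a reporter for Dazl, an RNA-binding protein of germ cells. A further 3 groups were GFP-positive cells sorted after differentiation away from feeder cells, which the labels call in vitro primordial germ cells (PGCs, the embryonic founders of sperm and eggs). These were Stella-GFP cells at day 7 and Dazl-GFP cells at day 12 and day 16. The remaining pair of groups were Dazl-GFP-positive germ cells sorted from gonads at the embryonic stage E13.5 and from testes of mice 7 to 11 days old, called juvenile testis here.

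The 75th percentile of the background-subtracted signal ranged from 103 to 474 across the arrays, and 50.6% to 68.9% of the spots on an array were well above background. Replicate arrays correlated across genes with a Pearson's r between 0.943 (E13.5) and 0.994 (day 7). The number of arrays limits the precision of every value. The labels do not say whether replicates are separate cultures or animals, so the p-values measure the spread between these samples only, which may be technical. Changes are given as log2 fold changes with their standard error from limma, over 2 arrays per group, and a gene was called at an adjusted p under 0.05 over 18876 genes. The members of a gene list that were called are counted over all genes, and adjusted over the list alone where that count differs. In each named gene called between 2 groups, every array of the higher group lay above every array of the lower group. The labels call all samples male. On the library labelled E13.5 replicate 1, however, the Y-linked genes Ddx3y and Eif2s3y were not well above background, though they were on every other array. Each count is thus also given without this library, whose spread enters the error all comparisons share. Replicates agreed least at E13.5, where this error and its p are likely too small.

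In the Stella-GFP line, the comparison of GFP-positive with GFP-negative ES cells asked which genes mark the ES cells that express Stella. Dppa3, a maternal-effect and early PGC gene, was higher in GFP-positive cells by 2.63 ± 0.35 (adjusted p = 0.0114), with mean log2 levels of 5.24 ± 0.14 and 2.61 ± 0.02 (SD, n = 2). Gpat3, an enzyme of glycerolipid synthesis, rose by 2.42 ± 0.25, and Tspan1, a tetraspanin, by 2.20 ± 0.32. Among the genes called lower, Fgf5, a marker of primed pluripotent cells, fell by 4.29 ± 0.69, Fgf8, a signal of the primitive streak, by 3.41 ± 0.35, and Foxa2, a transcription factor of endoderm, by 4.46 ± 0.68. The neural progenitor filament gene Nes (-1.30 ± 0.24), the epithelial keratin gene Krt8 (-2.57 ± 0.45) and the imprinted gene Magel2 (-1.82 ± 0.31) fell as well.

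Nek5, a protein kinase, was at least 4.65-fold higher and Pcdh7, a protocadherin, at least 1.62-fold higher (1.02-fold without GFP-positive replicate 2) in Stella-GFP-positive ES cells, both being not well above background in GFP-negative cells. Gbp2b, an interferon-induced GTPase, was at least 4.59-fold lower, a bound of 1.996-fold without GFP-negative replicate 1. Urgcp rose by 1.74 ± 0.29, and the zinc-finger gene Sall2 and the secreted kinase Pkdcc, which was well above background on 1 of the 2 GFP-positive arrays, changed by -2.71 ± 0.36 and -3.26 ± 0.51. Of the primed epiblast genes, 3 of 17 fell (9 adjusted over the list alone), among them Pou3f1 (-2.06 ± 0.34). The list was lower than other genes (median -1.05, adjusted p = 1.25e-11, or 0.0773 with an estimated correlation). The early PGC list was higher (median 0.54, adjusted p = 2.32e-06, or 0.0773 with an estimated correlation). Adjusted over the list alone 4 of 15 members were called, and over all genes only Dppa3, whose reporter set the gate. The mesoderm list (median -0.61, adjusted p = 0.00215) and the imprinted list (median -0.34, adjusted p = 0.00252) were lower, with 1 member of each called. The lists had adjusted p = 0.193 and 0.17 with an estimated correlation. Genes of the 2-cell-like state were lower (median -1.11, adjusted p = 4.28e-05), endoderm genes lower (median -0.10, adjusted p = 0.0259) and naive pluripotency genes higher (median 0.35, adjusted p = 0.0199), but all 3 turned direction under normexp background correction. An estimated correlation gave adjusted p = 0.0926, 0.135 and 0.415 in that order. limma called 0 of the 6 members of the 2-cell-like list, 4 adjusted over the list alone and 4 at an unadjusted p under 0.05. It called 0 of the 18 members of the naive list, with 3 higher and 1 lower at an unadjusted p under 0.05. The other 21 lists did not pass, the nearest being neural ectoderm (adjusted p = 0.0569). The median and the test differed in sign for the general pluripotency and endothelial lists.

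In all, limma called 83 genes in the Stella sort, 17 higher and 66 lower. Dppa3 was the only gene of the panel called: the changes of Dazl (0.21), Pou5f1 (-0.22), Nanog (0.38), Ddx4 (0.03) and Kit (0.99, adjusted p = 0.116) were not. Within the slides that held both gates Dppa3 differed by 2.55 and 2.71. The 16 named genes called had the same sign on both slides, which follows from the separation of their arrays and is no further check. With slide as a block 19 genes were called, 4 of the named ones among them. The count was 23 without GFP-negative replicate 1, 31 without GFP-negative replicate 2 and 257 without the library labelled E13.5 replicate 1. Of the named calls, 2 (Fgf8 and Gpat3) were kept whichever of the 4 libraries was left out. Kit was called without the E13.5 library. Mesoderm genes had 0 and 2 and endoderm genes 0 and 2 members higher and lower adjusted over the list alone. Leaving out 1 library also ended the list calls of endoderm (adjusted p = 0.113 without GFP-positive replicate 1 and 0.073 without GFP-positive replicate 2), imprinted genes (0.107 without GFP-positive replicate 2), and mesoderm (0.0609 without GFP-negative replicate 1 and 0.0829 without GFP-positive replicate 2). It ended that of naive pluripotency too (adjusted p = 0.0664 and 0.0737 without GFP-negative replicate 1 and 2, and 0.173 without GFP-positive replicate 1).

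In the Dazl-GFP line, the same sort asked which genes mark the ES cells that express Dazl. Dazl was higher in GFP-positive cells by 4.12 ± 0.16 (adjusted p = 3.57e-07), and by 4.08 and 4.15 within the slides. Its other tested probe rose by 1.83. Genes of germ cells rose with it, such as Stk31, a Tudor-domain kinase (1.67 ± 0.26), which was above background on 1 of the 2 GFP-negative arrays. Others were Dmrt1, a transcription factor of germ cells and testis (1.14 ± 0.21), Tdrd12, of the piRNA pathway that silences transposons (1.23 ± 0.25), and Stag3, a subunit of meiotic cohesin (1.29 ± 0.29). The piRNA helicase gene Mov10l1 and the meiotic co-chaperone gene Fkbp6 were at least 2.47-fold higher and at least 4.63-fold higher, not being well above background in GFP-negative cells. Naive pluripotency genes rose, including Klf2 (1.27 ± 0.21), Tbx3 (0.75 ± 0.16), Fbxo15 (1.30 ± 0.26) and Spp1 (1.80 ± 0.34), and so did Tet2, which oxidises methylcytosine (1.55 ± 0.25). The other tested probe of Klf2 changed by 0.145. Called lower were the primitive streak genes T (-3.66 ± 0.71), Mesp1 (-3.71 ± 0.58) and Fgf8 (-3.48 ± 0.35), and Foxa2 (-4.10 ± 0.68), Sox17 (-3.51 ± 0.67) and Gata6 (-3.74 ± 0.66), factors of endoderm, whose list did not pass (adjusted p = 0.258). The 3 tested probes of Gata6 ranged from -3.74 to -0.007.

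Among the lists of the Dazl sort, the naive pluripotency list had 6 of 18 members higher (10 adjusted over the list alone; median 1.15, adjusted p = 1.14e-09), the gonadal germ cell list 5 of 21 (8 adjusted over the list alone; median 0.71, adjusted p = 5.52e-07) and the piRNA list 3 of 20 (8 adjusted over the list alone; median 0.63, adjusted p = 0.00173). They had adjusted p = 0.0773, 0.134 and 0.415 with an estimated correlation. With dim genes at their bound the gonadal median was 1.05. The meiosis list had 1 of 30 higher (5 adjusted over the list alone; median 0.41, adjusted p = 0.00968, and adjusted p = 0.654 with an estimated correlation). Markers of other cells moved with these germ cell lists. Fibroblast genes were higher, 6 of 24 called and 13 adjusted over the list alone (median 1.20, adjusted p = 6.28e-11, or 0.169 with an estimated correlation). The collagen genes Col5a2 and Col1a1 rose by 2.76 ± 0.53 and 2.46 ± 0.50, the microfibril gene Fbn1 by 2.28 ± 0.40 and the mesenchymal factor Prrx1 by 2.04 ± 0.42. Macrophage genes were higher too, 2 of 12 called (median 0.86, adjusted p = 0.00541, or 0.348 with an estimated correlation). C1qc and Adgre1, however, were not well above background in either gate. The Hox list was higher (median 0.32, adjusted p = 0.0305, or 0.375 with an estimated correlation). Hoxa10 was at least 2.49-fold higher, but 7 of its 14 members were dim in both gates. Adjusted over the list alone, 4 and 0 of the macrophage genes, 2 and 0 of the Hox genes, 1 and 6 of the primed epiblast genes and 0 and 4 of the stress genes were higher and lower.

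Mesoderm genes were lower in Dazl-GFP-positive ES cells, 6 of 22 called with 1 higher (12 lower adjusted over the list alone; median -1.90, adjusted p = 5.25e-08, and adjusted p = 0.0773 with an estimated correlation), with Mixl1 at least 12.9-fold lower. Primed epiblast genes were lower (median -1.10, adjusted p = 0.000742, and adjusted p = 0.211 with an estimated correlation), with Fgf5 the member called (-3.18 ± 0.69). Imprinted genes (median -0.24, adjusted p = 0.0305) and stress and immediate-early genes (median -0.22, adjusted p = 0.0313) were lower. In that order, these lists had adjusted p = 0.327 and 0.415 with an estimated correlation. They included Magel2 (-1.84 ± 0.31) and Peg3 (-1.36 ± 0.29), with H19 higher, and Junb (-0.80 ± 0.16) and Atf3 (-1.66 ± 0.32). Flt1, the receptor of endothelial cells (-3.14 ± 0.60), Krt8 (-2.63 ± 0.45) and Nes (-1.51 ± 0.24) fell. The largest changes included Glipr1 at least 6.48-fold higher, the mast cell protease gene Mcpt8 at least 6.8-fold higher and the kidney progenitor factor Six2 at least 3.68-fold lower. The other 17 lists did not pass, the nearest being general pluripotency (adjusted p = 0.0755). For endoderm, trophoblast, Sertoli, Leydig, erythroid and glycolysis genes the median, mean and test differed in sign.

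limma called 542 genes in the Dazl sort, 279 higher and 263 lower (51.5% higher, against 32.0% of the 75 called with normexp background correction). Of the panel, Dppa3 (1.24, adjusted p = 0.101), Pou5f1 (0.22), Nanog (0.49), Ddx4 (0.67) and Kit (0.59) were not called. The 35 named genes called had the same sign on both slides. Slide as a block gave 182 genes and kept 19 of the 35 and 9 of 11 list calls. The count was 38 without GFP-negative replicate 1, 54 without GFP-negative replicate 2, 69 without GFP-positive replicate 1, 52 without GFP-positive replicate 2 and 1376 without the library labelled E13.5 replicate 1, which also brought in Dppa3. Of the named calls 4 (Dazl, Fgf8, Mcpt8 and Six2) were kept whichever of the 4 libraries was left out. The list calls of Hox (adjusted p = 0.11) and imprinted genes (0.0714) were lost without GFP-negative replicate 1, that of stress genes (0.051) without GFP-negative replicate 2, and those of Hox (0.124), imprinted (0.0748), macrophage (0.077) and stress genes (0.0781) without GFP-positive replicate 2.

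**Figure D1:**
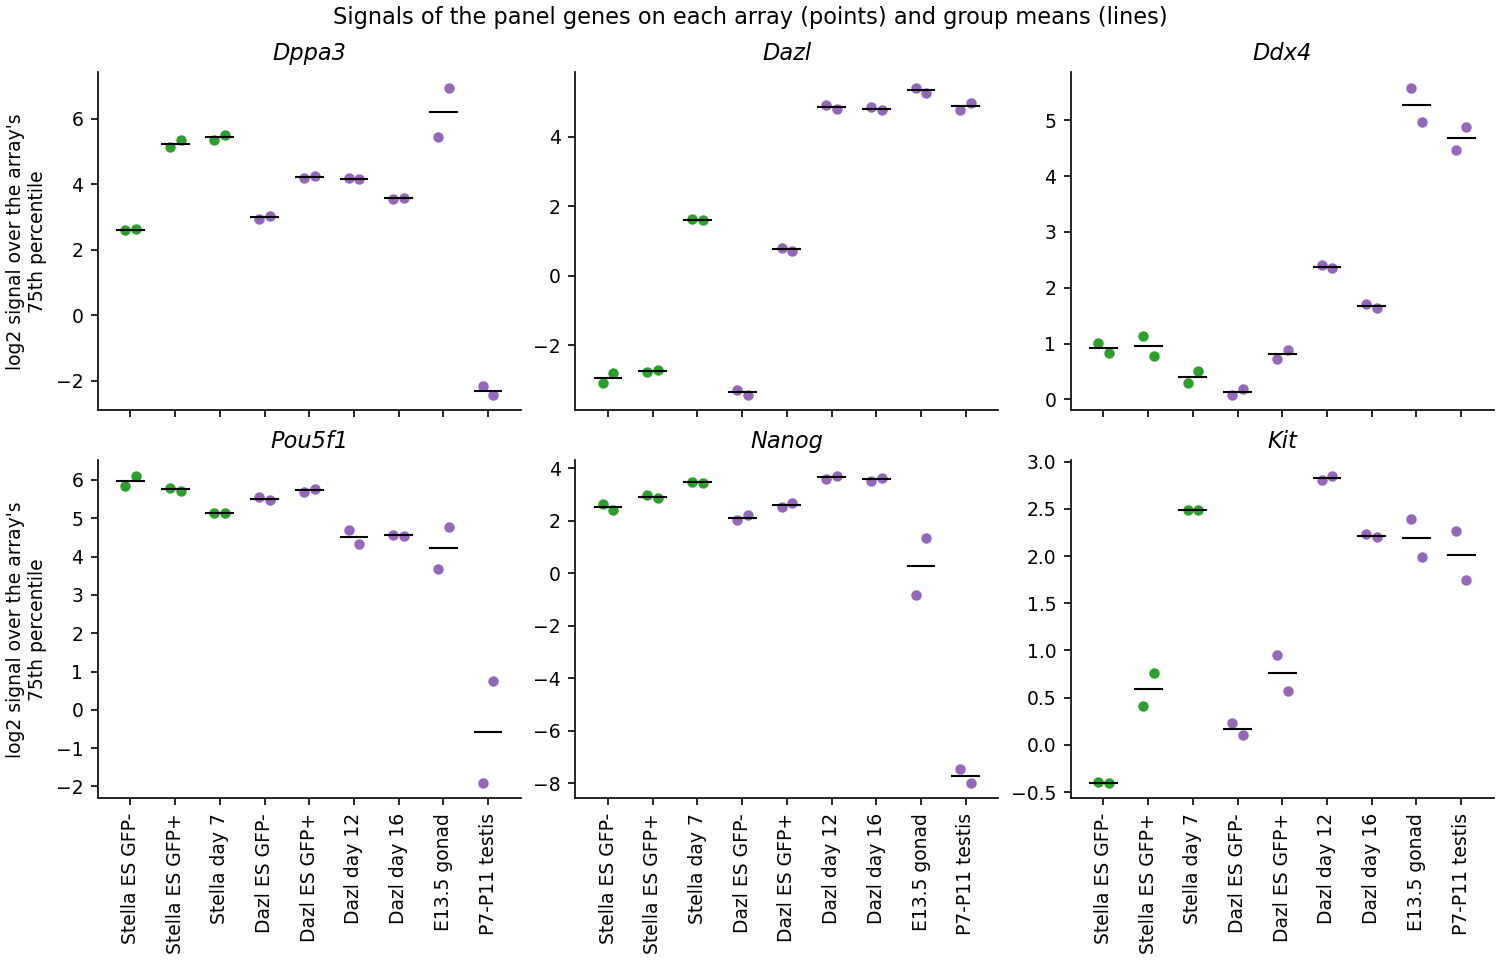
Signal of 6 genes on each array (log2 over the array's 75th percentile; points, replicate 1 on the left) and group means (lines) in the 9 groups, with Stella-GFP samples in green and Dazl-GFP samples in purple. Dppa3 averages -2.30 ± 0.18 and 6.19 ± 1.07 (SD, n = 2) in juvenile testis and E13.5 germ cells.

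The difference between the sorts, Stella minus Dazl, tested whether the reporters parted the ES cells along different genes. Dazl was called, by -3.91 ± 0.23 (adjusted p = 3.01e-05), and its 2 tested probes gave -3.91 and -1.155. Its own reporter set the gate of the Dazl sort, so this call does not answer the question. The gonadal germ cell and early PGC lists hold Dazl and Dppa3, and were not tested without them. Fcgrt, the neonatal Fc receptor, was called with it (-1.82 ± 0.23), its changes being 1.99 in the Dazl sort and 0.17 in the Stella sort. Angptl7, a secreted angiopoietin-like protein, the cytokine gene Tslp and Hoxd13, a limb patterning factor, were called in the same direction. No size is given for them, since Angptl7 and Tslp were not well above background in either Stella gate, nor Hoxd13 in Stella-GFP-positive cells. The remaining call of 6 was a transcript without a gene name, in the other direction, also not well above background in either Stella gate. Across genes, which are not independent replicates, the sorts correlated with a Pearson's r of 0.465 and a Spearman's rho of 0.385. They shared 41 genes lower, against 0.92 for independent calls, and 4 higher, against 0.251. limma's calls were opposite for 0 genes, and at an unadjusted p under 0.05 the difference itself gave 887 genes, no more than the 944 of 18876 expected by chance.

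Lists lower in the Stella sort than in the Dazl sort were fibroblast (median -1.22, adjusted p = 4.68e-10), naive pluripotency (median -0.69, adjusted p = 1.09e-06), and 2-cell-like genes (median -0.996, adjusted p = 8.56e-06). With an estimated correlation they had adjusted p = 0.178, 0.111 and 0.0821. Within the slides that held both gates, the mean change of the fibroblast list was 1.25 and -0.65 in the Stella sort and 1.42 and 1.43 in the Dazl sort. Also lower were gonadal germ cell (median -0.64, adjusted p = 1.58e-07) and piRNA genes (median -0.75, adjusted p = 9.22e-05). The lists had adjusted p = 0.125 and 0.327 with an estimated correlation. The mesoderm list was higher (median 0.93, adjusted p = 0.000301, and adjusted p = 0.135 with an estimated correlation), its medians being -0.61 in the Stella sort and -1.90 in the Dazl sort. The mesoderm call was lost when genes had to be well above background on every array compared (adjusted p = 0.144), and the piRNA call with normexp background correction (0.112). A further 7 lists passed. The Hox list, lower (median -0.31, adjusted p = 0.000186, and adjusted p = 0.134 with an estimated correlation), turned with that filter. Early PGC genes were higher (median 0.39, adjusted p = 0.0107, or 0.178 with an estimated correlation). Their call was lost without Stella GFP-negative replicate 1 (adjusted p = 0.0877) or GFP-positive replicate 2 (0.0811). Macrophage (median -0.67, adjusted p = 0.00178), primed epiblast (median -0.31, adjusted p = 0.0214), meiosis (median -0.45, adjusted p = 0.0471) and neural ectoderm genes (median -0.31, adjusted p = 0.0185) were lower, and stress genes higher (median 0.15, adjusted p = 0.0497). An estimated correlation gave adjusted p = 0.272, 0.415, 0.737, 0.134 and 0.419 in that order. Without Stella GFP-positive replicate 2 the macrophage, primed, meiosis and stress lists reached adjusted p = 0.179, 0.326, 0.197 and 0.536, and neural ectoderm 0.0858 without Dazl GFP-negative replicate 1. Naive pluripotency genes had 0 and 1, 2-cell-like genes 0 and 2, piRNA genes 0 and 1, mesoderm genes 3 and 1, Hox genes 0 and 5, macrophage genes 0 and 2 and neural ectoderm genes 0 and 1 members higher and lower adjusted over the list alone. The nearest of the 15 lists that did not pass was DNA methylation (1 lower adjusted over the list alone, adjusted p = 0.0693). Signs of median, mean and test differed for trophoblast, Leydig, cell cycle, apoptosis and glycolysis genes.

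limma called 6 genes in this difference, 1 higher and 5 lower, and 1 with slide as a block. The count was 13 without Stella GFP-negative replicate 1, 3 without GFP-negative replicate 2, 19 without GFP-positive replicate 1 and 9 without GFP-positive replicate 2. It was 1, 2, 1 and 1 without Dazl GFP-negative replicate 1 and 2 and GFP-positive replicate 1 and 2, and 76 without the library labelled E13.5 replicate 1. Of the genes named here, Dazl alone was called in each of these fits.

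Stella-GFP-positive cells at day 7 were compared with Stella-GFP-positive ES cells to ask what changed over the first days of differentiation. Dazl rose by 4.35 ± 0.16 (adjusted p = 1.91e-07) and Kit, the receptor on which PGCs depend, by 1.90 ± 0.22 (adjusted p = 0.000301). Germ cell genes rose with them, among them Gpat2 (3.88 ± 0.35) and Fkbp6 (4.15 ± 0.51) of the piRNA pathway, the meiotic cohesin genes Smc1b (4.49 ± 0.48) and Stag3 (2.43 ± 0.29) and the meiotic gene Hormad2 (3.58 ± 0.40). Sohlh2, a factor of early germ cell differentiation, rose by 1.97 ± 0.30, with Dmrt1 (2.05 ± 0.21), Mov10l1 (2.34 ± 0.38) and Stk31 (2.15 ± 0.26). Called lower, from lists that did not pass, were the de novo methyltransferase gene Dnmt3b (-2.71 ± 0.34), Uhrf1, a partner of maintenance methylation (-0.94 ± 0.19), and Lin28a (-1.99 ± 0.37). Also called lower were Pou3f1 (-2.39 ± 0.34), Klf4 (-1.36 ± 0.24), Mycn (-1.43 ± 0.31) and Myc (-3.39 ± 0.39). Of the panel, Dppa3 (0.19), Pou5f1 (-0.61), Nanog (0.54) and Ddx4 (-0.55, adjusted p = 0.111) were not called.

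At day 7, the lists that rose were gonadal germ cell (8 of 21 members higher and 2 lower, median 0.71, adjusted p = 0.000297), piRNA (7 of 20 higher and 1 lower; median 0.70, adjusted p = 0.00309) and meiosis genes (6 of 30 higher and 2 lower; median 1.32, adjusted p = 0.0012). They had adjusted p = 0.26, 0.419 and 0.599 with an estimated correlation. Fibroblast genes moved the other way, 13 of 24 lower and 14 adjusted over the list alone (median -1.64, adjusted p = 7.17e-05, and adjusted p = 0.415 with an estimated correlation). With dim genes at their bound the median was -1.41. Examples were S100a4 (-7.02 ± 0.64), Acta2 (-1.70 ± 0.29), and the collagen cross-linking enzyme Lox, at least 4.38-fold lower, or 1.64-fold without ES replicate 1. The matrix protease gene Mmp3 was at least 35.0-fold lower, the matrix protein gene Mgp at least 19.9-fold lower and the chemokine gene Ccl2 at least 28.1-fold lower. The largest rises were in the X-linked genes Xlr5d and Xlr5c and in Asb9 and Hrc, at least 20.2-fold, 8.66-fold, 19.6-fold and 38.5-fold. Ccdc116 was at least 14.5-fold lower. The other 24 lists did not pass, general pluripotency being the nearest (4 of 14 lower, adjusted p = 0.0631). Of DNA methylation genes 2 were higher and 6 lower (adjusted p = 0.224), and of cell cycle genes 6 of 29 lower (adjusted p = 0.155), among them Ccne1 (-2.93 ± 0.26) and Pcna (-0.82 ± 0.17). Of naive pluripotency genes 1 was higher and 4 lower (adjusted p = 0.133), among them Socs3 (-2.68 ± 0.42). Adjusted over the list alone, 3 and 8 of the DNA methylation genes, 0 and 7 of the cell cycle genes and 1 and 7 of the naive pluripotency genes were higher and lower. The median, mean and test differed in sign for spermatogonia, imprinted, endoderm, Leydig and macrophage genes.

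limma called 3891 genes at day 7, 1438 higher and 2453 lower, or 37.0% higher, against 48.5% with quantile normalization (3585 genes) and 48.6% with normexp background correction (828 genes). The day 7 arrays alone filled their slides, with their own scan day and extraction protocol, so the slide and the group cannot be told apart. The count was 1439 without day 7 replicate 1 and 1717 without replicate 2, and 5694 without the library labelled E13.5 replicate 1, where Ddx4 and Nanog were called. Of the 32 named calls, 29 were kept whichever of the 4 libraries was left out, Mycn, Pcna and Uhrf1 being lost.

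Dazl-GFP-positive cells at day 12 were compared with Dazl-GFP-positive ES cells, the same question at a later stage. Dazl was again higher, by 4.11 ± 0.16 (adjusted p = 9.86e-08), with Kit (2.07 ± 0.22, adjusted p = 7.26e-05) and Ddx4, an RNA helicase of gonadal germ cells (1.57 ± 0.23, adjusted p = 0.000585). On the slide that held arrays of both groups these differed by 4.08, 2.28 and 1.46. Stra8, the gene that retinoic acid induces at the entry into meiosis, rose by 8.95 ± 1.73. Genes of the piRNA pathway and of meiosis rose, such as Fkbp6 (7.60 ± 0.51), Gpat2 (5.70 ± 0.35) and Mael (3.44 ± 0.35), and Smc1b (4.93 ± 0.48) and Stag3 (3.095 ± 0.29). The transcription factors Sohlh2 (4.94 ± 0.30) and Dmrt1 (3.11 ± 0.21) were called higher too. The germ cell gene Asz1, the synaptonemal complex gene Tex12 and the testis ADP/ATP carrier gene Slc25a31 were at least 20.6-fold higher, 11.2-fold higher and 51.1-fold higher, respectively. Genes of the 2-cell-like state, a rare state of ES cells that resembles the early embryo, rose as well: Tcstv1 by 6.91 ± 0.44, Tcstv3 by 5.60 ± 0.29, Usp17la by 6.03 ± 0.35 and Zfp352 to at least 11.4-fold higher.

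Gonadal germ cell genes had 15 of 21 members higher at day 12 than in ES cells (median 3.11, adjusted p = 8.08e-10), and piRNA genes 13 of 20, with Tdrd12 lower (median 1.67, adjusted p = 1.15e-07). In that order, these lists had adjusted p = 0.0926 and 0.17 with an estimated correlation. Meiosis genes had 14 of 30 higher, with Mlh3 lower (median 2.38, adjusted p = 3.28e-06), and 2-cell-like genes 5 of 6 (median 5.58, adjusted p = 3.01e-06). With an estimated correlation they had adjusted p = 0.419 and 0.0773. Primed epiblast genes fell, 11 of 17 (median -2.30, adjusted p = 8.8e-05), and so did general pluripotency genes, 5 of 14 (median -0.94, adjusted p = 0.00139), and mesoderm genes, 8 of 22 (median -1.68, adjusted p = 0.00447). The lists had adjusted p = 0.17, 0.486 and 0.211 with an estimated correlation. Among them were Pou3f1 (-3.90 ± 0.34), Dnmt3b (-3.61 ± 0.34), Foxd3 (-3.80 ± 0.42), Lin28a (-3.77 ± 0.37) and Mycn (-2.21 ± 0.31). Of mesoderm, Fgf8 fell (-2.87 ± 0.35), T was at least 11.8-fold lower and Meox1 at least 3.55-fold lower. Markers of other cells fell beside the rise of the germ cell lists. Of the fibroblast genes 17 of 24 fell (median -3.37, adjusted p = 4.68e-10), and of the macrophage genes 4 of 12 (median -1.22, adjusted p = 0.0236). An estimated correlation gave adjusted p = 0.178 and 0.415 in that order. With dim genes at their bound the medians were -2.85 and -0.78, 6 macrophage genes being dim in both groups. S100a4 (-9.97 ± 0.64) and Col5a2 (-5.14 ± 0.53) fell, and Lox, Prrx1 and the lysozyme gene Lyz2 were at least 40.1-fold lower, 19.7-fold lower and 81.2-fold lower. Gonadal germ cell genes had 16 and 1, piRNA genes 14 and 2, meiosis genes 15 and 1, 2-cell-like genes 5 and 1, primed epiblast genes 1 and 12 and general pluripotency genes 0 and 6 members higher and lower adjusted over the list alone.

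The largest changes at day 12 included Ambp, a plasma protein precursor, at least 216-fold higher, Asb9, at least 206-fold higher, Xlr5d, at least 124-fold higher, the melanin enzyme gene Dct, at least 106-fold higher, and Ccdc172, at least 49.2-fold higher. Ccl2, the caveolin gene Cav1, Mgp and Mmp3 were lower by at least 388-fold, 352-fold, 319-fold and 199.7-fold. These falls may come from feeders among the ES cells. Dnmt3l (-2.49 ± 0.40) and Myc (-5.85 ± 0.39) fell. The other 19 lists did not pass, the nearest being the cell cycle list (5 of 29 lower, adjusted p = 0.17), with Leydig (2 of 10 higher, adjusted p = 0.306) and imprinted genes (5 higher and 6 lower, adjusted p = 0.983) among them. Median, mean and test differed in sign for spermatogonia, spermatid, germline RNA-binding, stress and glycolysis genes. limma called 5152 genes, 2466 higher and 2686 lower, or 47.9% higher, against 37.0% with low signals floored (6421 genes) and 35.6% with no filter on dim probes (6645 genes). Dppa3 (-0.05), Pou5f1 (-1.22, adjusted p = 0.174) and Nanog (1.05, adjusted p = 0.14) were not called, Nanog being called without the library labelled E13.5 replicate 1 (adjusted p = 0.00143). With slide as a block 2886 genes were called, and all 42 named calls were kept there and whichever of the 4 libraries was left out. The count was 2660 and 2786 without ES cell replicate 1 and 2, 2556 and 2789 without day 12 replicate 1 and 2, and 6925 without the library labelled E13.5 replicate 1. The macrophage call was lost without day 12 replicate 1 (adjusted p = 0.0617) or ES cell replicate 2 (0.0614).

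The day 7 and day 12 changes, each against the ES cells of its own line, went together across 18876 genes, with a Pearson's r of 0.562 and a Spearman's rho of 0.508. They had 820 genes higher in both, against 188 for independent calls, and 1224 lower in both, against 349, while 60 went opposite ways, against 525. Genes are not independent replicates, so no p is given, and the comparisons shared no array. ES cell arrays of one stood on slides with arrays of the other, and with no slide shared r was 0.531. With 1 library of either comparison left out, r ranged from 0.417 to 0.628, the ends being without Stella-GFP-positive ES replicate 1 and 2. The fibroblast list averaged 0.37 and -0.78 in those libraries. Fibroblast genes fell in both changes, and r was not computed without them.

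**Figure D2:**
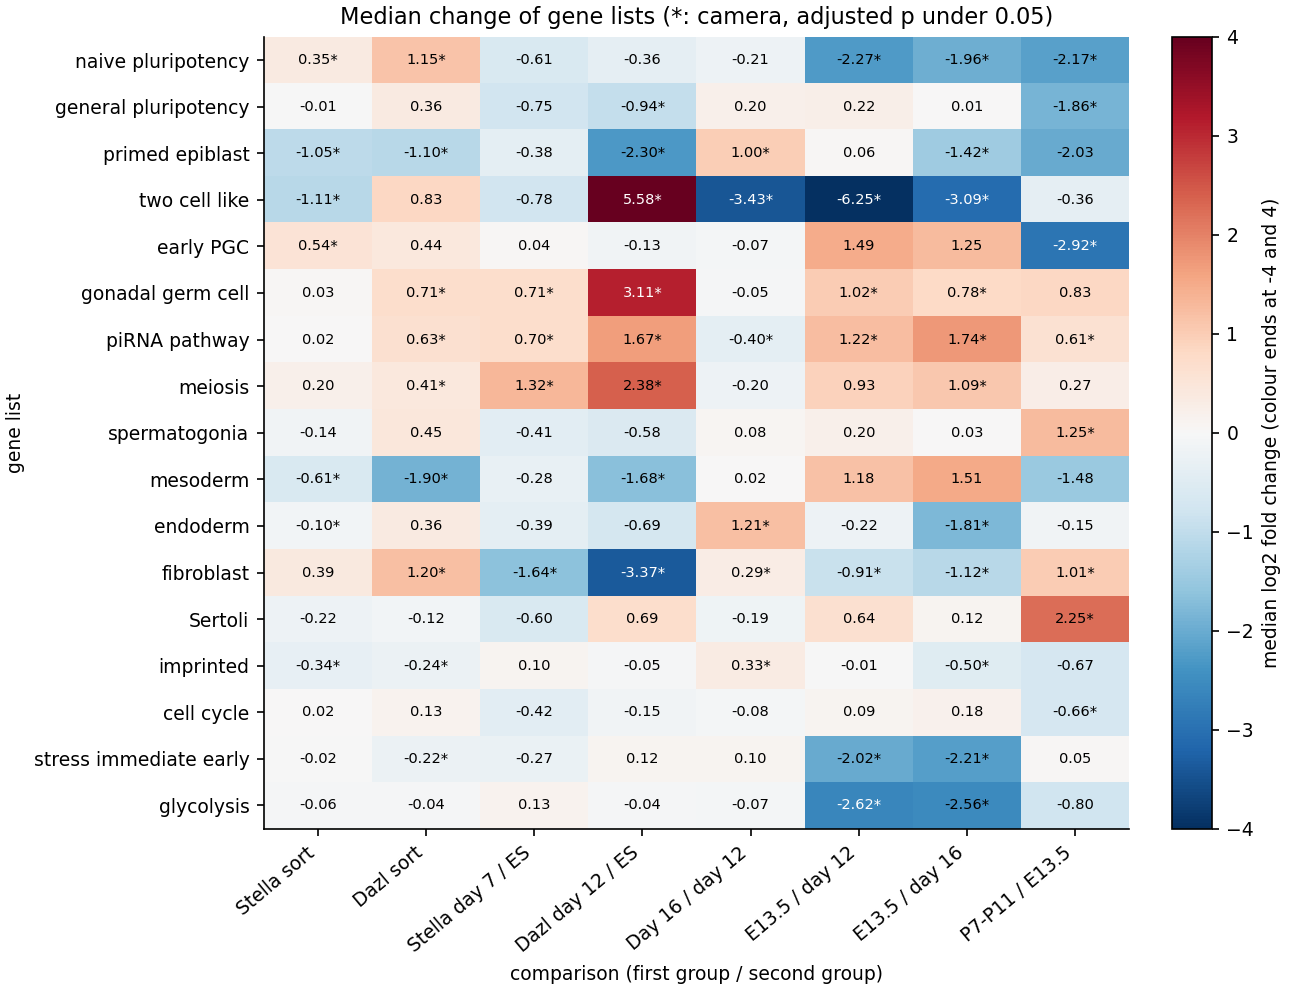
Median log2 fold change of the members of 17 gene lists (vertical axis) in 8 comparisons (horizontal axis), red higher and blue lower in the group named first, with a star where camera passed an adjusted p of 0.05. The medians span -6.25 to 5.58, both of 2-cell-like genes, and the starred Stella sort values of naive pluripotency, 2-cell-like and endoderm genes turn direction with normexp background correction.

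Day 16 was compared with day 12 to ask what changed as the Dazl-GFP culture went on. No gene of the panel was called: Dppa3 (-0.61), Dazl (-0.05), Pou5f1 (0.05), Nanog (-0.07), Ddx4 (-0.71, adjusted p = 0.318) and Kit (-0.61, adjusted p = 0.425) were all short of the threshold. Lens crystallins, the structural proteins of the eye lens, rose, Cryba1 by 7.16 ± 0.51 (adjusted p = 6.91e-05) and Cryaa by 6.79 ± 0.42 (adjusted p = 2.78e-05), or 6.90 and 6.67 within the slides. Crybb1 was at least 49.6-fold higher, and the lens channel gene Mip at least 13.1-fold higher. The 2-cell-like genes that had risen by day 12 fell, with Tcstv1 at -4.04 ± 0.44 (-4.10 and -3.98 within the slides). Tcstv3 (-3.97 ± 0.29), Pramel37 (-3.83 ± 0.29), Zfp352 (-3.29 ± 0.39) and Usp17la (-2.96 ± 0.35) fell with it.

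The list of 2-cell-like genes was lower at day 16 than at day 12, 5 of 6 called (median -3.43, adjusted p = 2.84e-15), and the endoderm list higher, 3 of 22 called and 9 adjusted over the list alone (median 1.21, adjusted p = 6.46e-10). They had adjusted p = 0.00885 and 0.00885 with an estimated correlation. These were the only 2 of the 81 list calls in the 9 comparisons that held with an estimated correlation. Of endoderm, Dab2, an endocytic adaptor, rose by 2.23 ± 0.22, and Cubn, an endocytic receptor, was at least 91.3-fold higher. Neural ectoderm genes were higher, 2 of 17 called (median 0.15, adjusted p = 0.00173), as were primed epiblast genes (median 0.9996, adjusted p = 3.01e-06) and imprinted genes (median 0.33, adjusted p = 0.000137). In that order, these lists had adjusted p = 0.0847, 0.125 and 0.12 with an estimated correlation. Adjusted over the list alone, 3 and 0 of the primed epiblast genes and 4 and 0 of the imprinted genes were higher and lower. The eye and brain factor Pax6 (1.32 ± 0.21) and Stmn2 (1.14 ± 0.22) rose, Fgf5 was at least 3.95-fold higher and Mirg at least 3.88-fold higher. piRNA genes were lower (median -0.40, adjusted p = 0.00618) and fibroblast genes higher (median 0.29, adjusted p = 0.023). With an estimated correlation they had adjusted p = 0.447 and 0.603. limma called 0 members of either, and of them 2 piRNA genes were lower and 2 fibroblast genes higher adjusted over the list alone, while at an unadjusted p under 0.05, 6 piRNA genes were lower and 0 higher, and 6 fibroblast genes higher and 2 lower. Cyp4f14 was at least 15.7-fold higher, Srgn rose by 2.54 ± 0.42 and Lgals6 fell by 3.83 ± 0.48. The other 21 lists did not pass, gonadal germ cell (adjusted p = 0.435) and meiosis genes (adjusted p = 0.482) among them. Signs of median, mean and test differed for mesoderm, Sertoli, Leydig and macrophage genes.

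limma called 189 genes between day 16 and day 12, 115 higher and 74 lower, or 60.8% higher, against 76.8% of 6970 with normexp background correction. With slide as a block 131 genes were called, 16 of the 18 named ones among them, and all 18 had the same sign on both slides. The count was 72 and 82 without day 12 replicate 1 and 2, 59 and 62 without day 16 replicate 1 and 2, and 374 without the library labelled E13.5 replicate 1. Cubn, Fgf5, Mirg, Pax6, Srgn and Stmn2 were lost in at least 1 of the first 4 of these. The fibroblast call was lost without day 12 replicate 2 (adjusted p = 0.0606) or the E13.5 library (0.066), and the piRNA call without day 12 replicate 1 (0.0986).

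**Figure D3:**
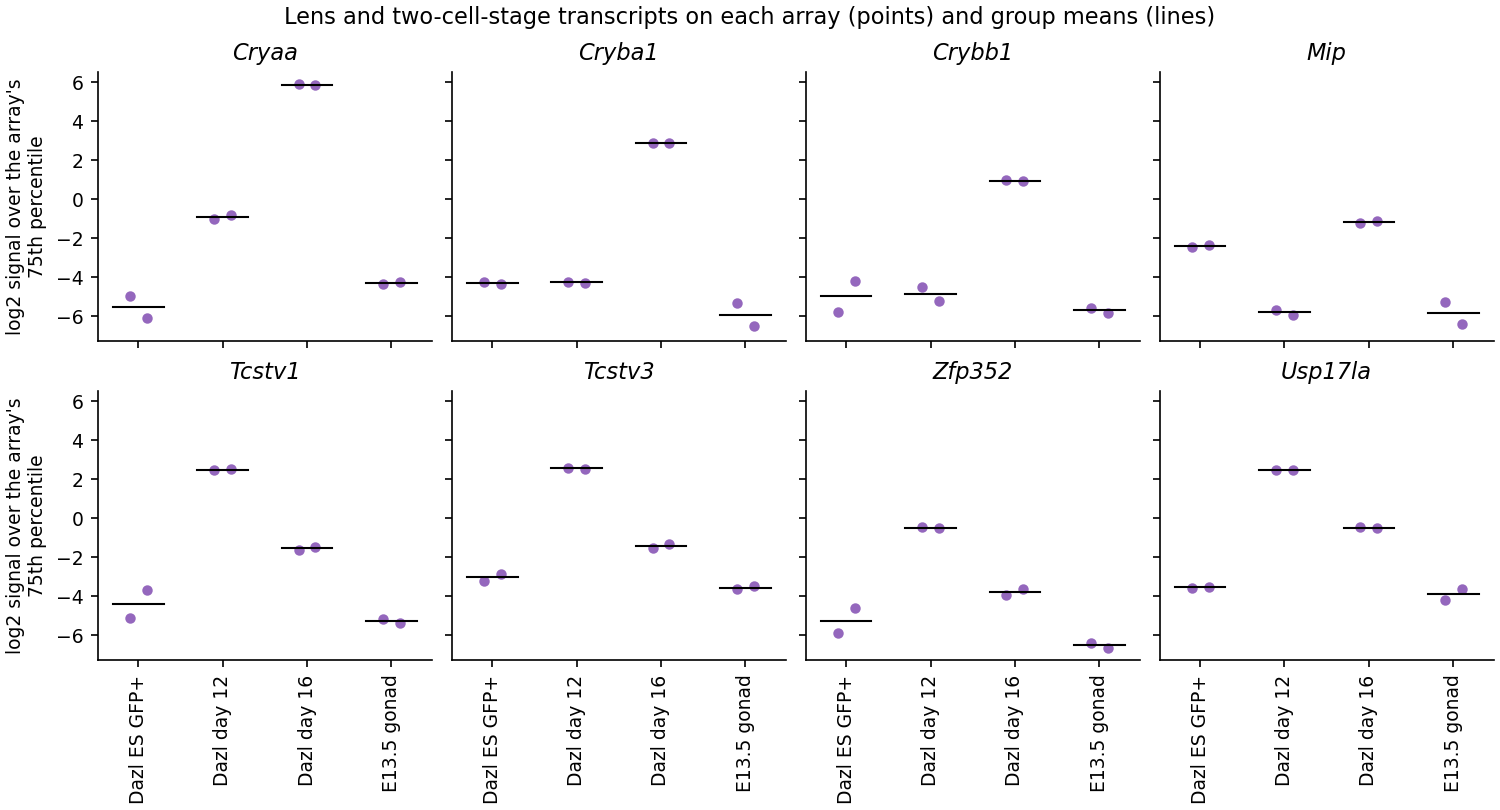
Signal of 4 lens genes (upper panels) and 4 genes of the 2-cell-like state (lower panels) on each array (log2 over the array's 75th percentile; points) and group means (lines) in 4 groups of the Dazl-GFP line. Cryaa lies higher at day 16 than at day 12 by 6.79, and Tcstv1 lower (-4.04).

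Germ cells from E13.5 gonads were compared with the day 12 cells to ask how the cultured cells differed from germ cells of the embryo. Ddx4 was higher at E13.5 by 2.90 ± 0.23 (adjusted p = 4.25e-06) and Dppa3 by 2.02 ± 0.35 (1.26 without E13.5 replicate 2). Nanog fell by 3.39 ± 0.49 (E13.5 SD 1.54, n = 2). Called higher were Tdrd1 (5.08 ± 0.27), Tdrkh (2.51 ± 0.19) and Tdrd7 (2.87 ± 0.33), Tudor-domain genes of the piRNA pathway and germ granules. Dnd1, which protects germ cell mRNAs, rose by 3.34 ± 0.40, as did Stk31 (1.91 ± 0.26), Cpeb1, a regulator of polyadenylation (3.19 ± 0.37), and Lin28a (2.96 ± 0.37). Bnc1, a zinc-finger gene of germ cells, was at least 31.8-fold higher, Khdc1a at least 43.8-fold higher, and Isl2 rose by 5.83 ± 0.41. Naive pluripotency genes were lower, such as Spp1 (-7.92 ± 0.34), Tbx3 (-7.83 ± 0.16) and Socs3 (-6.39 ± 0.42). So were the 2-cell-like genes Zscan4c (-8.00 ± 0.47), Usp17la (-6.39 ± 0.35) and Tcstv1, at least 215-fold lower.

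Naive pluripotency genes had 12 of 18 members lower at E13.5 than at day 12 (median -2.27, adjusted p = 2.42e-06) and glycolysis genes 14 of 19, with Eno3 higher (median -2.62, adjusted p = 3.97e-07). The lists had adjusted p = 0.12 and 0.125 with an estimated correlation. Stress and immediate-early genes had 17 of 20 lower, with Dnajb1 higher (median -2.02, adjusted p = 1.23e-06), and 2-cell-like genes 5 of 6 (median -6.25, adjusted p = 3.18e-05). An estimated correlation gave adjusted p = 0.111 and 0.0926 in that order. Examples were the glucose transporter gene Slc2a3 (-3.30 ± 0.19), the lactate transporter gene Slc16a3 (-4.61 ± 0.28) and Pgk1 (-2.76 ± 0.20). Of the stress list, examples were Hspb1 (-4.54 ± 0.38), Junb (-2.61 ± 0.16) and Klf6 (-2.62 ± 0.19). piRNA genes were higher, 11 of 20, with Gtsf1 lower (median 1.22, adjusted p = 0.00173), as were gonadal germ cell genes, 10 of 21, with Dpep3 and Dmrt1 lower (median 1.02, adjusted p = 0.0114), and germline RNA-binding genes, 14 of 29 against 3 lower (median 0.70, adjusted p = 0.0305). They had adjusted p = 0.415, 0.419 and 0.135 with an estimated correlation. Beside them fibroblast genes were lower, 9 of 24 against 1 higher (median -0.91, adjusted p = 0.0185, and adjusted p = 0.599 with an estimated correlation), with Tagln (-4.18 ± 0.33) and Postn (-3.14 ± 0.57). The erythroid list (5 of 9 higher, adjusted p = 0.0693), with the globin gene Hba-a1 (3.29 ± 0.45), did not pass. The remaining lists did not pass either, the nearest being meiosis (10 of 30 higher, adjusted p = 0.0532), with endothelial genes (2 higher and 4 lower, adjusted p = 0.345) among them. Median, mean and test differed in sign for general pluripotency, primed epiblast, DNA methylation, Sertoli and Leydig genes. Gonadal germ cell genes had 13 and 2, piRNA genes 12 and 1, meiosis genes 9 and 0, 2-cell-like genes 1 and 5 and erythroid genes 6 and 1 members higher and lower adjusted over the list alone.

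The E13.5 libraries differed between themselves in meiotic genes: Stra8 stood at 8.88 on the log2 scale in the library labelled replicate 1 and 1.55 in replicate 2, and Sycp3, of the synaptonemal complex, at 1.13 and -1.77. Of the members of the DNA methylation list, which did not pass (adjusted p = 0.601), the histone methyltransferase gene Ehmt2 rose by 1.89 ± 0.21 and Mbd3 by 1.79 ± 0.23, and Dnmt3l and Dnmt3b changed by -6.24 ± 0.40 and -2.72 ± 0.34. Ambp (-8.58 ± 0.80) and Dct (-8.14 ± 0.42), which had risen by day 12, were lower, Pramel37 at least 94.5-fold lower and the small heat-shock gene Hspb8 at least 128-fold lower. Dazl was called higher (0.48 ± 0.16, adjusted p = 0.0314) and Kit lower (-0.64 ± 0.22, adjusted p = 0.0376), and Pou5f1 (-0.29) was not called. The probes of Dazl differ in sign, and its change turned to -0.18 with the mean over probes. limma called 7930 genes, 4336 higher and 3594 lower, and 8103 without the library labelled E13.5 replicate 1. The E13.5 and juvenile arrays shared a slide and a scan day that held no cultured cells, so slide and group cannot be told apart here. Leaving out 1 library ended the calls of Dazl and Kit, that of germline RNA-binding genes without day 12 replicate 2 (adjusted p = 0.0642) and that of gonadal germ cell genes without the library labelled E13.5 replicate 1 (0.132).

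**Figure D4:**
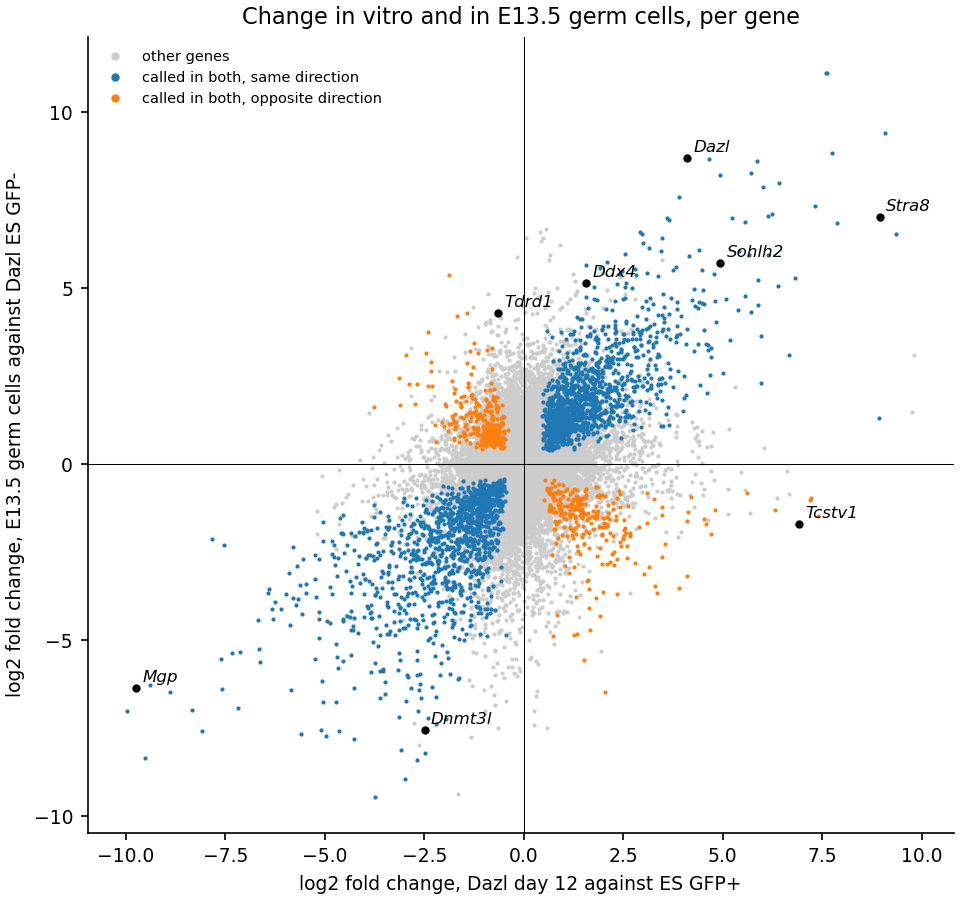
Log2 fold change of each of 18876 genes at day 12 against Dazl-GFP-positive ES cells (horizontal axis) and in E13.5 germ cells against Dazl-GFP-negative ES cells (vertical axis), in blue where called in both the same way and in orange where called in opposite ways. The Pearson's r across these genes is 0.457, and 540 genes are orange.

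To ask whether the cultured cells changed in the direction of embryonic germ cells, the change from Dazl-GFP-positive ES cells was set against that of E13.5 cells from Dazl-GFP-negative ES cells, so that the changes shared no array. Across genes, which are not independent replicates, they correlated with a Pearson's r of 0.457 and a Spearman's rho of 0.369 at day 12, and 0.437 and 0.356 at day 16. At day 12, 1269 genes were higher in both, against 581 for independent calls, 1254 lower in both, against 544, and 540 opposite, against 1132. At day 16 these were 1039 against 493, 1155 against 521, and 540 against 1030. Without the library labelled E13.5 replicate 1, r was 0.371 at day 12 and 0.365 at day 16, and with normexp background correction 0.543 and 0.12. Some arrays of the changes stood on shared slides, and with slides not shared r at day 12 was 0.439. The fibroblast list averaged 1.46 and 0.035 in GFP-positive and GFP-negative ES cells. At day 12, day 16 and E13.5 it averaged -1.62, -1.14 and -2.34. The list fell in each change, and r was not computed without its genes.

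Against the day 16 cells, E13.5 germ cells again had more Ddx4 (3.61 ± 0.23) and Dppa3 (2.62 ± 0.35) and less Nanog (-3.32 ± 0.49). Tdrd1 (5.83 ± 0.27), Tdrd5 (4.41 ± 0.41), Tdrkh (2.93 ± 0.19) and Dnd1 (3.28 ± 0.40) rose, Bnc1 was at least 33.1-fold higher and Khdc1a at least 45.5-fold higher. The lens genes of the day 16 cells were lower at E13.5, Cryaa (-10.17 ± 0.42) and Cryba1, by at least 8.23 on the log2 scale. The endoderm list fell, 10 of 22 against 1 higher (11 lower adjusted over the list alone, median -1.81, adjusted p = 0.00139), and so did imprinted genes, 9 of 28 against 1 higher (median -0.50, adjusted p = 0.00984). In that order, these lists had adjusted p = 0.0807 and 0.213 with an estimated correlation. Examples were Dab2 (-3.38 ± 0.22), Apoe (-3.02 ± 0.35) and the collagen gene Col4a1 (-2.78 ± 0.33), and the imprinted Sgce (-5.20 ± 0.35) and Impact (-3.07 ± 0.23).

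The lists called between day 12 and E13.5 were called the same way against day 16, except germline RNA-binding (adjusted p = 0.0706). Lower were naive pluripotency (12 of 18; median -1.96, adjusted p = 3.01e-06), 2-cell-like (median -3.09, adjusted p = 0.00208) and fibroblast genes (15 of 24; median -1.12, adjusted p = 0.000298). With an estimated correlation they had adjusted p = 0.122, 0.148 and 0.419. With dim genes at their bound the 2-cell-like median was -2.79. Examples were Tbx3 (-8.03 ± 0.16), Spp1 (-7.43 ± 0.34), Socs3 (-5.73 ± 0.42) and Tagln (-3.33 ± 0.33). Stress (16 of 20; median -2.21, adjusted p = 2.88e-07) and glycolysis genes (14 of 19; median -2.56, adjusted p = 1.23e-06) were lower. The lists had adjusted p = 0.0926 and 0.134 with an estimated correlation. They included Junb (-2.86 ± 0.16), Klf6 (-2.83 ± 0.19), Slc2a3 (-3.40 ± 0.19), Slc16a3 (-4.50 ± 0.28) and Pgk1 (-2.56 ± 0.20). piRNA (12 of 20; median 1.74, adjusted p = 0.000186) and gonadal germ cell genes (10 of 21; median 0.78, adjusted p = 0.00858) were higher. An estimated correlation gave adjusted p = 0.354 and 0.415 in that order. Meiosis genes were also higher, 11 of 30 (median 1.09, adjusted p = 0.0236, and adjusted p = 0.713 with an estimated correlation), with Stag3 (1.58 ± 0.29) and the synaptonemal complex gene Syce1 (1.86 ± 0.40, or 1.07 without the library labelled E13.5 replicate 1). Neural ectoderm genes (median -1.24, adjusted p = 0.0127), Hox genes (median -1.18, adjusted p = 0.0358; median -1.60 at the bound) and primed epiblast genes (median -1.42, adjusted p = 0.0413) were lower. They had adjusted p = 0.125, 0.398 and 0.426 with an estimated correlation. Stmn2 (-4.08 ± 0.22) fell, and the neural factor Zic1 was at least 17.8-fold lower. Of the 15 lists that did not pass, erythroid genes had 4 of 9 higher (adjusted p = 0.124), with Hba-a1 up by 3.37 ± 0.45. Signs of median, mean and test differed for general pluripotency, spermatogonia, spermatid, DNA methylation and Sertoli genes. Adjusted over the list alone, 1 and 12 of the naive pluripotency genes, 13 and 1 of the piRNA genes, 1 and 18 of the stress genes and 1 and 8 of the neural ectoderm genes were higher and lower.

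Dct (-8.55 ± 0.42) and Dnmt3l (-7.63 ± 0.40) fell between day 16 and E13.5, and Eprn and the interferon-induced gene Usp18 were at least 156-fold lower and 75.8-fold lower. Dazl was called higher (0.53 ± 0.16), with probes of differing sign and -0.11 with the mean over probes, while Pou5f1 (-0.34) and Kit (-0.02, which turned to 0.66 with normexp background correction) were not called. limma called 8018 genes, 4552 higher and 3466 lower, or 56.8% higher, against 35.1% of 13778 with normexp background correction, and 8134 without the library labelled E13.5 replicate 1. No slide held both groups, so slide and group cannot be told apart, and the count was 5345 without day 16 replicate 1. Without the library labelled E13.5 replicate 1 the calls of meiosis (adjusted p = 0.851), gonadal germ cell (0.0822) and primed epiblast genes (0.588) were lost. So were that of Hox genes without E13.5 replicate 2 (0.185), that of primed epiblast genes without day 16 replicate 1 (0.063) and that of Dazl when 1 of the 4 libraries was left out.

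Germ cells of the juvenile testis were compared with those of the E13.5 gonad to follow the cells from the fetal gonad into the postnatal testis. Dppa3 (-8.49 ± 0.35, adjusted p = 1.12e-07) and Pou5f1 (-4.80 ± 0.62) were called lower. Nanog and Sox2 were at least 62.3-fold lower and 194-fold lower. Ifitm1 (-6.34 ± 0.35), Ifitm3 (-4.11 ± 0.30), Esrrb (-5.10 ± 0.31), Tdh (-4.68 ± 0.33) and Utf1 (-4.40 ± 0.48) fell with them, and Gdf3 was at least 66.1-fold lower. Genes of spermatogonia rose, with Gfra1, the receptor of the stem cell factor GDNF, at least 17.7-fold higher, Bcl6b at least 38.3-fold higher, and Ccnd2 (4.17 ± 0.55) and Dmrt1 (1.64 ± 0.21) higher. So did the piRNA genes Piwil1 (2.61 ± 0.26), Tdrd9 (4.17 ± 0.54) and Tdrd1 (1.83 ± 0.27).

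Early PGC genes had 12 of 15 members lower in the juvenile testis and 1 higher (median -2.92, adjusted p = 6.25e-06), and general pluripotency genes 9 of 14 lower (11 adjusted over the list alone; median -1.86, adjusted p = 3.18e-05). In that order, these lists had adjusted p = 0.0773 and 0.415 with an estimated correlation. Naive pluripotency genes had 12 of 18 lower and 4 higher (median -2.17, adjusted p = 0.0166), and trophoblast genes 6 of 15 lower (median -1.79, adjusted p = 0.0358), with Rhox6 (-6.73 ± 0.91). With an estimated correlation they had adjusted p = 0.407 and 0.38. Cell cycle genes had 17 of 29 lower (median -0.66, adjusted p = 0.000252, and adjusted p = 0.202 with an estimated correlation), with Ccnb2 (-1.34 ± 0.17), Ccne1 (-1.84 ± 0.26) and Mcm3 (-0.98 ± 0.15). Spermatogonia genes had 11 of 25 higher and 3 lower (median 1.25, adjusted p = 0.0305; median 0.58 with dim genes at their bound) and piRNA genes 5 of 20 higher (median 0.61, adjusted p = 0.0236). The lists had adjusted p = 0.419 and 0.56 with an estimated correlation. Of the lists of somatic cells, macrophage (4 of 12 lower, median -0.73, adjusted p = 0.108), erythroid (median -0.76, adjusted p = 0.273), Leydig (median 0.26, adjusted p = 0.941) and endothelial genes (median 1.07, adjusted p = 0.176) did not pass. Higher were Sertoli genes, with 10 of 19 higher and 1 lower (median 2.25, adjusted p = 0.00771), and fibroblast genes, with 9 of 24 higher and 1 lower (median 1.01, adjusted p = 0.00464). An estimated correlation gave adjusted p = 0.56 and 0.56 in that order. Clu (4.42 ± 0.87, or 2.74 without the library labelled E13.5 replicate 1), Inha (3.13 ± 0.59), Ctsl (1.60 ± 0.28) and Col1a1 (3.84 ± 0.50) rose, Fbn1 was at least 7.21-fold higher, and Rhox5 fell (-6.46 ± 0.69). Cell cycle genes had 0 and 18, trophoblast genes 1 and 6, spermatogonia genes 11 and 4, Sertoli genes 12 and 1, fibroblast genes 10 and 1 and spermatid genes 0 and 0 members higher and lower adjusted over the list alone. Of 28 lists 19 did not pass, the nearest being Hox (adjusted p = 0.0569), with spermatid (2 of 8 higher, adjusted p = 0.577) and apoptosis genes (adjusted p = 0.435) among them. Median, mean and test differed in sign for endoderm, neural ectoderm and Leydig genes.

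Rbmy, a Y-linked gene of spermatogenesis, rose by 10.49 ± 1.15 in juvenile testis over E13.5, where it was well above background on replicate 2 only, and by 7.92 against replicate 2 alone. Cst12 (8.26 ± 0.62), Esx1 (7.98 ± 1.03), Radx (6.74 ± 0.36), Svs5, at least 106-fold higher, and Tmem132e, at least 51.6-fold higher, were among the largest rises, with Rhox9 (-7.45 ± 0.88) among the largest falls. Dnmt3b rose by 3.48 ± 0.34 and Tet1, which oxidises methylcytosine, changed by -2.60 ± 0.38. Dazl was called lower (-0.47 ± 0.16, adjusted p = 0.0414), with probes of differing sign and a change of 0.023 under quantile normalization, and Ddx4 (-0.60, adjusted p = 0.0623) and Kit (-0.19) were not called. Both groups lay on 1 slide, so slide as a block (5796 genes, 36 of the 37 named) could not shift their difference. limma called 6578 genes, 3016 higher and 3562 lower, and far fewer in fits of these arrays alone. The count was 7611 without the library labelled E13.5 replicate 1. Without it the calls of Sertoli (adjusted p = 0.233) and trophoblast genes (0.254) were lost, and without E13.5 replicate 2 that of piRNA genes (0.156). Also lost were, without juvenile replicate 1, those of Sertoli (0.0928) and trophoblast genes (0.0618), without juvenile replicate 2, those of naive pluripotency (0.0569), piRNA (0.207), spermatogonia (0.234) and trophoblast genes (0.135), and that of Dazl in at least 1 of these.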

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

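The test of array slides and the fibroblast list outside the 28 lists, both used in this part, were chosen after the rise of the fibroblast genes was seen. The change from GFP-negative to GFP-positive ES cells differed between the Stella-GFP and Dazl-GFP lines, by limma's test of the difference itself (Stella minus Dazl, log2), for 6 genes: Dazl (-3.91), Angptl7 (-3.42), Tslp (-2.76), Hoxd13 (-2.59), Fcgrt (-1.82) and a transcript without a gene name (2.80). The call of Dazl follows from the sorting, as its own reporter set the Dazl gate. At an unadjusted p under 0.05 limma gave 887 genes, against 944 expected by chance. Only Dazl (-1.155 by its other probe) and Fcgrt have a measured size, the others being dim in Stella-GFP-positive cells. Dazl alone was called with each library left out, the count being 1 without Dazl GFP-negative replicate 1 or either Dazl GFP-positive replicate, 2 and 3 without Dazl and Stella GFP-negative replicate 2, 13 and 19 without Stella GFP-negative and GFP-positive replicate 1, and 76 without the library labelled E13.5 replicate 1.

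By camera's test of the same difference, medians were lower for the fibroblast (-1.22), 2-cell-like (-0.996), piRNA (-0.75), naive pluripotency (-0.69), macrophage (-0.67), gonadal germ cell (-0.64), meiosis (-0.45), neural ectoderm (-0.31), primed epiblast (-0.31) and Hox lists (-0.31, turning direction with the filter on every array compared), and higher for the mesoderm (0.93), early PGC (0.39) and stress lists (0.15). None of these 13 list calls held with an estimated correlation (lowest adjusted p = 0.0821). The gonadal and early PGC lists hold Dazl and Dppa3. Without Stella GFP-positive replicate 2 the calls of the macrophage, primed epiblast, meiosis, stress and early PGC lists were lost (adjusted p = 0.179, 0.326, 0.197, 0.536 and 0.0811), and that of neural ectoderm without Dazl GFP-negative replicate 1 (0.0858).

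The fibroblast genes higher in the Dazl-GFP-positive gate may come from feeder fibroblasts, on which the labels say the ES cells grew, although a sort on the reporter should remove cells that lack it. Of 35 fibroblast genes outside all 28 lists, 33 were tested. Their median change was 1.95 (bootstrap SD 0.23, with 12 called higher and 25 adjusted over the list alone). It was 0.34 in the Stella sort, where the fixed list's mean change was 1.25 and -0.65 on the 2 slides. No list p is given, as the list was chosen after fibroblast genes were seen to rise. Feeder cells and expression by the ES cells would both raise it. Col1a1, an abundant fibroblast transcript, averaged 3.29 ± 0.12 and 0.83 ± 0.07 (SD, n = 2) in the GFP-positive and GFP-negative gate. A difference between array slides is argued against, the fixed list's mean change being 1.42 and 1.43 on the slides that held both gates. Expression of these genes by the Dazl-positive ES cells themselves stays open, and no biological explanation was tested.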

How the results depend on the processing

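The leaving out of the library labelled E13.5 replicate 1 from comparisons that do not use it, and the agreements without shared slides, were chosen after the data were seen. Of 246 alternatives for the counts, the list total and the agreements, 162 left them within 1.5 times or the replicate spread and 84 did not. Of 4122 alternatives for the 258 calls of named genes, 3562 kept the call, 557 lost it and 3 turned it. For these and the lists, 5305 of 6136 values stayed on their side of the threshold, 803 fell short, 20 newly passed and 8 turned. Unless a cause is given here, the cause was not tested.

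In the order of the results, limma called 83, 542, 6, 3891, 5152, 189, 7930, 8018 and 6578 genes. These counts moved by over 1.5 times as follows. normexp background correction gave 9 in the Stella sort, 75 in the Dazl sort, 0 in their difference (limma, 193 at an unadjusted p under 0.05, where chance would give 944), 828 at day 7, 1458 at day 12, 6970 at day 16 against day 12 and 13778 at E13.5 against day 16; it fitted a background mean of -261 on day 16 replicate 2, against -108 to 13.04 on the other arrays, which shrinks that array's log2 5th to 90th percentile range to -0.34 to 1.13 from -7.08 to 2.27. Quantile normalization gave 18 in the difference, floored low signals 40, the intensity trend 1, the slide block 1 and the filter on every array compared 2. No filter gave 55 in the Stella sort and that filter 53, and 102 at day 16 against day 12. The slide block gave 19, 182 and 2886 in the Stella sort, the Dazl sort and at day 12. A fit of only the arrays compared gave 0 in the Stella sort (limma, 1189 at an unadjusted p under 0.05), 2637 in the Dazl sort, 3 in the difference, 9240 at day 12, 3720 at day 16, 2392 and 3237 at E13.5 against day 12 and day 16, and 363 in juvenile testis.

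With the replicate number as a block in such a fit, the counts were 0 in the Stella sort, the Dazl sort, the difference, at day 16 and in juvenile testis (limma, 2804, 6509, 1675, 7395 and 4864 at an unadjusted p under 0.05), 600 at day 7, 7791 at day 12, and 594 and 1354 at E13.5 against day 12 and day 16. These fits have fewer arrays to set the spread. Replicate deviations correlated across genes between -0.034 and 0.558, over 2 pairs in each comparison, too few to show that the numbers pair the samples. The deposited table, with 13533 genes, gave 31 in the Stella sort, 249 in the Dazl sort, 1762 at day 7, 2690 at day 12, 90 at day 16, 4598 and 4690 at E13.5 against day 12 and day 16, and 3722 in juvenile testis. The replicate number in the fit of all 18 arrays and a log2 fold change of at least 1 moved no count by that much.

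With 1 library left out, the lone sample of a group being assumed to vary like the other groups, the counts ranged from 23 to 257 in the Stella sort, 38 to 1376 in the Dazl sort, 1 to 76 in the difference, 1439 to 5694 at day 7, 2556 to 6925 at day 12, 59 to 374 at day 16, 5451 to 8167 and 5345 to 8433 at E13.5 against day 12 and day 16, and 5960 to 7611 in juvenile testis. The highest counts of the first 6 comparisons came without the library labelled E13.5 replicate 1, which none of them compares, through the spread the groups share. The lowest counts came without a replicate 1 in the Stella sort and the Dazl sort (GFP-negative), at day 7, at day 12, and at day 16 against day 12 or E13.5 (day 16). The agreements ranged from 0.417 to 0.628 (day 7 with day 12), 0.371 to 0.479 (day 12 with E13.5) and 0.365 to 0.448 (day 16 with E13.5). The first moved to 0.669 with normexp, 0.496 with no filter and 0.624 with the filter on every array, the second to 0.543 with normexp and 0.369 as Spearman's rho, and the third to 0.461 with quantile normalization, 0.12 with normexp and 0.356 as Spearman's rho.

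Of 81 list calls, 2 held with an estimated correlation; 65 were kept with fry, 65 with normexp, 53 of 56 with the slide block and 54 of 75 with the deposited table, while the total stood at 73 to 87 with 1 library left out. In the Stella sort, the endoderm (adjusted p = 0.715), 2-cell-like (0.715) and naive pluripotency lists (0.506) turned with normexp, and in the difference the Hox list (0.77) with the filter on every array. Dazl turned at E13.5 against day 12 (-0.18) and day 16 (-0.11) with the mean over probes and in juvenile testis (0.023) with quantile normalization, and Kit at E13.5 against day 16 (0.66) with normexp. The share of higher calls moved at day 7 from 36.96% to 48.45%, and in the difference from 16.67% to 50% (9 of 18), with quantile normalization. The median change of all genes moved at day 7 from -0.15 to -0.02 with quantile normalization and to -0.41 with normexp, at day 12 from -0.11 to 0.02, -0.31 and, with no filter, -0.40, and at E13.5 against day 16 from 0.19 to 0.13 and -0.54. Signal over background limits dim genes: with a median spot signal of 17 to 63 over background per array, folds against a dim group are lower bounds, and changes among dim genes cannot be measured.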

Other observations

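The tests of a poorer array, of mixed cells and of array slides in this part were chosen after the result was seen, and so were the gene lists used with the crystallins. Genes of the retinal pigment epithelium also moved at day 16, with 2 of 13 called higher than at day 12 and 3 adjusted over the list alone (median 0.60, adjusted p = 1.44e-06, and adjusted p = 0.0289 with an estimated correlation), and with photoreceptor (median -0.03, adjusted p = 0.8), skeletal muscle (-0.37, 0.157) and liver genes (-0.16, 0.435) short of the threshold. By camera the retinal pigment list was also higher in the Dazl sort (median 0.32, adjusted p = 0.0114, or 0.186 with an estimated correlation). There 3 of 13 were called higher, and 5 were higher and 1 lower adjusted over the list alone. In E13.5 germ cells the lens crystallins were lower than at day 16, 9 of 11 called (median -4.68).

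In the library labelled E13.5 replicate 1, the Y-linked genes Ddx3y, Eif2s3y and Kdm5d stood at -7.45, -7.29 and -7.25 on the log2 scale, against -1.36, 3.17 and -1.82 in replicate 2. A poorer array or poorer RNA is argued against, since 0.0616% of genes as bright in replicate 2 fell as far as the Y-linked gene that fell least, and so is a mixture of cells of XY and XX animals, since 0 of the 3 Y-linked genes were well above background. X-linked genes lay higher in this library than in replicate 2 relative to autosomal genes, by a median of 0.49 (bootstrap SD 0.0562; 475 and 13192 genes), against -0.02 to 0.10 in other groups, which is consistent with cells of XX animals in place of XY animals. Xist gives no support for this, its only probe well above background standing at -4.32 and -4.70 in replicates 1 and 2 and at -3.38 in juvenile testis replicate 1, while the meiotic genes Stra8 (8.88 and 1.55), Rec8 (7.45 and 3.14) and Sycp3 (1.13 and -1.77) were higher in it as well, and Nanog (-0.82 and 1.35) and Nanos2 (-5.63 and 0.39) lower. The X-linked genes gave a test of XX cells, but the labels name no female group to set beside this library. Ddx3y and Eif2s3y were well above background on every other array, from ES cells to juvenile testis. For these genes that argues against another stage of XY embryos alone, although not against a stage difference beside XX cells. A mislabelled sample stays open, and no other biological explanation was tested.

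The lens crystallins that rose at day 16 (7 of 11 called and 9 adjusted over the list alone, median 3.85, with no list p given, as the list was chosen because crystallins rose) may mark lens-forming cells carried into the gate, although a sort on the reporter should remove them. A difference between array slides is argued against, the crystallins' mean rise being 3.71 and 3.81 on the slides that held both days. Lens genes other than crystallins had a median change of 0.60 (bootstrap SD 0.508; 2 of 13 called and 4 adjusted over the list alone, adjusted p = 8.91e-06, and adjusted p = 0.0745 with an estimated correlation), between the bounds of 0.5 and 1 set before the test, which keeps this open. Cryaa averaged 5.87 at day 16 and -0.92 at day 12, and Maf, a transcription factor of the lens, 0.89 and 0.70. As that median decides neither way, lens-forming cells and crystallin expression in the Dazl-positive cells cannot be told apart, and no biological explanation was tested.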
